A study of Mus musculus with 6 samples.

How the data were processed

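Gene expression was measured in mouse haematopoietic stem and progenitor cells carrying the surface markers cKit and Sca1 and lacking lineage markers, called KSL cells. Per the labels' protocols, mice with floxed Runx1 and Runx3 genes and the Mx1-Cre transgene were compared with littermates without the transgene, on a C57BL/6 background reached by at least 3 generations of backcrossing. Mx1-Cre is a recombinase gene under an interferon-responsive promoter, and pIpC is a double-stranded RNA analogue that induces it. Per the labels' protocols, mice received 600 µg of pIpC on 7 alternate days from 4 weeks of age. The protocol text is the same for both groups, and the time from the last injection to cell collection is not given in the sources used here. RNA was amplified with NuGEN's WT-Ovation Pico system, labelled with biotin and hybridised to Affymetrix GeneChip Mouse Gene 1.0 ST arrays, per the labels' protocols.

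The deposited values were log2 signals at the level of whole genes, 1 per probe set and array. The sample titles name the gene-level default of RMA, a method that corrects background, equalises the arrays by quantiles and summarises probes, whereas the design text of the series names preliminary MAS 5.0 normalisation. Affymetrix Expression Console 1.0 was used, per the submitters' processing notes. The deposited values ran from 1.25 to 13.7 with array medians of 5.88 to 5.91 and nearly equal quartiles, as log2 RMA values do and linear MAS 5.0 values do not. Background settings, annotation version and genome build are not given in the sources used here, so no genome positions are stated. A gene-level signal averages probes along a whole transcript, which matters for a gene that lacks only some of its exons.

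The table held 35556 probe sets, of which 21789 were paired with 1 gene symbol, 1621 with several and 12146 with none in the platform annotation used. Probe sets with exactly 1 symbol were kept, and of several probe sets for a gene the one with the highest mean over the 6 arrays was used, which left 19938 genes. Entrez numbers of 19856 of these were found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. No filter on dim signals was applied. Groups came from the labels, 3 samples each, and no array duplicated another, the smallest SD of the difference between 2 arrays being 0.276 on the log2 scale. The number of arrays limits the precision of every value.

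The deposited values were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes at default settings, as DKO minus WT, two-sided. Adjusted p-values of genes are Benjamini-Hochberg adjusted over the genes tested, those of gene lists over the lists and those of gene families over the families. The threshold was 0.05. Standard errors are those of the fit, moderated with 5.52 prior degrees of freedom beside 4 residual ones. An exact permutation test of 3 samples against 3 cannot give a p below 0.1 and was not used for single genes. The script was tested on simulated data for this comparison over 19938 genes with 200 changed. It recovered 99% of changes of 1 on the log2 scale and 67% of changes of 0.5, and called 22 unchanged genes. These 22 were a larger share of its calls than the 0.05 that the threshold aims at. With no change simulated it made 0 calls. The simulated noise was independent between genes, so these rates may not hold for the arrays.

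The gene lists, the test, the rule for named genes and the alternatives, except where stated otherwise, were fixed before the data were examined. Of 634 list members, 584 were matched to a tested gene. The other 50, of which 13 lay in probe sets with several symbols, are not analysed here. They include Runx2, Ly6a, Cdkn1a and Bax. The 29 lists were tested with limma's camera, which asks whether a list's genes shifted more than all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Genes of the sex chromosomes were listed too but not tested as a group. Camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes moved to 1 side on balance, served as alternatives. Counts adjusted over the list alone use only the genes of that list in the adjustment.

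Named genes are the Runx family, the 12 largest rises and 12 largest falls among genes past the threshold whose DKO and WT values did not overlap, and up to 4 members of each list with the smallest p, with the members that moved most in a called list. Predicted genes, pseudogenes, snoRNAs and microRNAs were left out of the 12 rises and falls. Cd34, Cxcr4, Mcpt8, Prss34, Fcer1a, Pf4 and Ppbp, and members of gene families in the closing section, fall outside this rule and were chosen after their values were seen. Alternatives were quantile normalisation, median centring, cyclic loess, filters on dim genes, other choices of probe set, limma with a trend and robust settings, array weights, the replicate number as a block, other thresholds and each sample left out in turn. A fit without genes on chromosomes X and Y and a fit with the trend of each array over gene span and signal removed were added after the data had been seen. The alternatives for linear values were not run, because the values were already log2.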

Results

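The data were 6 arrays of KSL cells, 3 from mice labelled Runx1 and Runx3 double knockout (DKO) and 3 from wild-type littermates (WT). The labels describe each as an independent biological replicate. Each WT sample was pooled from 3 mice per the labels, and pooling of the DKO samples was not stated. The design text counts 6 mice in all, which conflicts with such pools, so whether a value with n = 3 stands for single mice or for pools is unsettled. KSL cells are the bone marrow fraction that holds haematopoietic stem cells and the earliest progenitors. Over all 19938 genes, Pearson correlations between arrays were 0.994 to 0.995 within the DKO samples, 0.99 to 0.991 within the WT samples and 0.976 to 0.98 between the groups. The median SD of a gene was 0.0985 within DKO and 0.125 within WT on the log2 scale.

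The single comparison of the design asks which genes differ in KSL cells after deletion of Runx1 and Runx3. These are 2 transcription factors of the blood system that bind DNA with the partner protein Cbfb. Since the WT littermates lacked the Mx1-Cre transgene, effects of the deletion and of the transgene cannot be told apart. The targeted genes came first as a check of the labels. Runx1 signal (probe set 10441003) was 9.29 ± 0.08 in the DKO-labelled samples and 8.47 ± 0.08 in WT (SD, n = 3), a rise of 0.82 on the log2 scale (SE 0.089, limma adjusted p = 0.000427) seen in 3 of 3 samples. Runx3 signal (probe set 10509030) was 7.38 ± 0.03 and 7.53 ± 0.06, a difference of -0.15 that did not pass (adjusted p = 0.253), with 3 of 3 DKO values below the WT values. Removal of a trend with gene span and signal, an alternative added after the data were seen, moved Runx1 to 0.50 (adjusted p = 0.00452, beside 0.000227 to 0.00452 over 18 alternatives) and Runx3 to -0.30 (adjusted p = 0.0362, beside 0.0362 to 0.46). Cbfb differed by -0.35 (adjusted p = 0.114) and passed the threshold with quantile normalisation (adjusted p = 0.019), cyclic loess (0.0223) and the trend removed (0.0147, at -0.57), in a range of 0.0147 to 0.292, and it was at -0.20 without WT replicate 2. A gene-level signal that includes probes outside the deleted exons cannot check a deletion, and probe positions and deleted exons were not used here. DKO and DKO-labelled therefore both mean samples labelled DKO, and every direction given is that of the labels.

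In the DKO-labelled samples, the largest rises included genes of mast cells, platelets and cell contacts, and the largest falls included genes of lymphoid and granulocytic progenitors. Cpa3, a mast cell carboxypeptidase, rose 10.7-fold (10.96 ± 0.09 against 7.54 ± 0.14, adjusted p = 5.6e-07). Cd200r3, a receptor of the CD200 receptor family, rose 12.3-fold (adjusted p = 2.74e-06), and its paralog Cd200r4 rose 8.54-fold, with the split between these similar genes uncertain. Their WT signals of 4.06 and 3.78 lay below the lower quartile of every array, so the size of these folds and their rank are uncertain. Ms4a2, the beta chain of the high-affinity IgE receptor, rose 4.72-fold (adjusted p = 0.000683). Cxcr2, a chemokine receptor of neutrophils, rose 9.61-fold, the tight junction protein Tjp1 8.61-fold and the platelet glycoprotein Gp5 6.99-fold. Plxdc2, the protocadherin Pcdh7, the interferon-inducible Ifi209, the junctional adhesion molecule Jam3 and the phospholipid enzyme Lpcat2 completed the 12 largest rises, with 6.1-fold, 6.03-fold, 5.88-fold, 5.47-fold and 5.15-fold. Ifi209 belongs to a family of similar genes, which leaves its own share of that signal uncertain.

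Bex1 fell by 3.11 on the log2 scale (SE 0.157, adjusted p = 1.04e-05) and Rpph1, the RNA component of ribonuclease P, fell by 3.04 (SE 0.163). Dntt, the polymerase that adds bases to antigen receptor genes in lymphocyte precursors, fell by 2.50 (7.14 ± 0.76 against 9.63 ± 0.20, adjusted p = 0.000788). Il18r1, a cytokine receptor chain, fell by 2.37 to 4.25, a signal below the lower quartile of every array that leaves the size uncertain, and the neutrophil elastase gene Elane fell by 2.30 (adjusted p = 4.67e-05). The apoptosis inhibitor Bcl2 fell by 2.12, from 9.02 ± 0.02 in WT to 6.90 ± 0.39. Ptpn3, Ak4, Hp, Cd72, Maged1 and Car1 completed the 12 largest falls, with changes of -2.26, -2.09, -2.05, -2.05, -2.03 and -2.02, where Ptpn3 was at -1.25 with the mean of its probe sets.

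**Figure D1:**
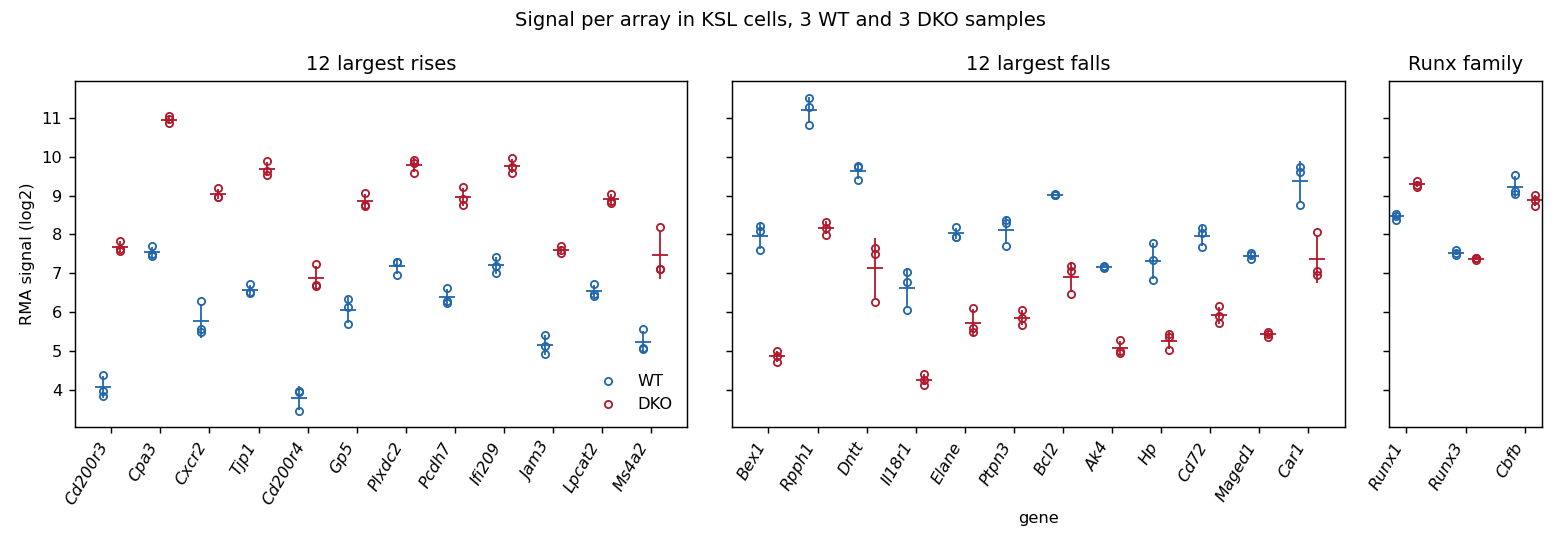
RMA signal (log2) of each array for the 12 largest rises, the 12 largest falls and the Runx family in 3 WT and 3 DKO samples, with open circles for arrays and bars for the mean and SD. Cpa3 lies at 10.96 in DKO and 7.54 in WT, Bex1 at 4.85 and 7.97, and Runx1 is higher in the 3 DKO samples.

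In total 1936 genes rose and 1533 fell, together 17.4% of 19938, while 16469 did not pass, and 6168 genes had an unadjusted p under 0.05. At least 2-fold changes were called for 222 genes that rose and 110 that fell. DKO and WT values did not overlap in 1934 and 1526 of the called genes, and in 35.8% of all genes, where chance gives 10%. The count of genes that rose was 1250 without DKO replicate 3, and the count that fell was 843, 876 and 854 without DKO replicates 1, 2 and 3. Calls were uneven over signal: of the 10% of genes with the strongest signal 29.2% rose and 9% fell, and of the 10% with the weakest 0.8% and 3.3%. Fold changes also followed gene span, with a Spearman rho of 0.146 across all genes, which are not independent replicates. With the trend over span and signal removed, 1476 genes rose and 1519 fell.

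Among the gate markers, the genes of the surface proteins used to sort or divide KSL cells, 4 of 6 rose and 1 fell, the same with adjustment over the list alone. Slamf1, a stem cell marker, rose by 1.95 on the log2 scale (adjusted p = 6.39e-05), Cd48 by 1.46, Ptprc by 0.76 and Kit, the sorted receptor itself, by 0.73. Flt3, a receptor of multipotent and lymphoid progenitors, fell by 1.32 (adjusted p = 0.000434), and Cd34 differed by 0.02 (adjusted p = 0.902). With the trend over span and signal removed, Kit was at 0.43 and Ptprc at 0.44, both past the threshold. The list was called higher (camera adjusted p = 0.0093, and adjusted p = 0.308 with an estimated correlation), and its call was also lost without the dimmest 50% of genes (0.0695), on ranks (0.104) and with the trend removed (0.0555, where the mean went from 0.60 to 0.40).

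The stem cell list was not called (adjusted p = 0.844), with 5 of 27 members rising, 5 falling and 17 not passing, and 5 and 8 when adjusted over the list alone. Its mean was 0.03, its median -0.12 and the direction of its test downward. Slamf1 and Tek, an angiopoietin receptor, rose by 1.95 and 1.64, whereas Ndn and Thy1 fell by 1.62 and 1.09, with the signal of Ndn in DKO (4.29) also below the lower quartiles. Of 18 listed Hox genes and cofactors 1 rose and 17 did not pass, the same over the list alone (mean -0.07, adjusted p = 0.361). The mean was -0.03 with cyclic loess or the trend removed. Of all measured Hoxa, Hoxb and Hoxd genes, some outside the list, 0 of 10, 1 of 9 and 1 of 10 fell. Camera and fry both pointed downward, 13 of the 18 members had a negative difference, and fry called the list lower (adjusted p = 0.0238, in a range of 0.0238 to 0.702). The one that rose was Meis1, a cofactor of Hox proteins (0.88, adjusted p = 0.0027), which was at 0.53 with the trend removed. Hoxb7, Hoxb3 and Hoxb2 differed by -0.35, -0.26 and -0.24 without passing (adjusted p = 0.0668, 0.059 and 0.092). Hoxb7 passed without WT replicate 1 (adjusted p = 0.0325, in a range of 0.0325 to 0.186), without the dimmest 50% of genes and with array weights, and was at -0.23 without WT replicate 3. Hoxb3 passed without the dimmest 25% or 50% of genes and with the trend removed (0.0352 to 0.181 over its alternatives). Of 24 cytokine receptors 7 rose, 5 fell and 12 did not pass (adjusted p = 0.469), and 8 and 5 when adjusted over the list alone. Csf2rb2 and Csf2rb, near-identical beta chains whose signals cannot be fully separated, rose 4.13-fold and 2.83-fold, and Flt3 and Il18r1 were among the falls.

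Mast cell genes moved in both directions. Of 17 members of the mast cell and basophil list 6 rose, 3 fell and 8 did not pass, with 6 and 4 over the list alone, and the mean was 0.43 ± 1.17 (SD over members). Beside Cpa3 and Ms4a2, the monoamine transporter Slc18a2 rose by 1.46, the histamine-forming enzyme Hdc by 1.27 and Csf1 by 0.75. The basophil protease genes Mcpt8 and Prss34 fell by 1.32 and 0.82, and Fcer1a by 0.68, whose call was lost without any 1 of the DKO replicates (adjusted p = 0.124, 0.0786 and 0.126, in a range of 0.0122 to 0.126) and whose value was -0.41 without WT replicate 2. Fcer1a signals, 3.85 in DKO and 4.53 in WT, lay below the lower quartile of every array. The size of its fall is thus uncertain. The list was called higher (adjusted p = 0.0415, and adjusted p = 0.308 with an estimated correlation). Its adjusted p was 0.0529 without DKO replicate 1 and 0.0584, 0.0549 and 0.076 without WT replicates 1, 2 and 3. The call was also lost on ranks (0.177), with all probe sets (0.0796) and without the dimmest 50% of genes (0.14), where the mean was 0.94, beside 0.75 without the dimmest 25%.

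Platelet and megakaryocyte genes rose in 10 of 19 cases, with 0 falls and 9 not passing, and 11 rises and 2 falls over the list alone. Gp5 rose by 2.80, Treml1, a platelet granule receptor, 2.83-fold (adjusted p = 0.000302), Plek by 1.29 and the integrin chain Itga2b by 0.92. Clec1b differed by 1.28 without passing (adjusted p = 0.0653), and it passed without DKO replicate 3 (1.84, adjusted p = 0.00325) and with the replicate number as a block (0.00507), in a range of 0.00325 to 0.201. Pf4 and Ppbp, abundant platelet chemokine genes, differed by -0.51 and -0.44 and did not pass (adjusted p = 0.256 and 0.427), and both depended on single samples. Without DKO replicate 2 they were at -0.79 and -0.89, where Ppbp passed (adjusted p = 0.0323, in a range of 0.0323 to 0.955), and without DKO replicate 3 at -0.16 and -0.03. The list mean was 0.53 ± 0.81 (adjusted p = 0.000213, and adjusted p = 0.512 with an estimated correlation).

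Granulocyte-monocyte progenitor genes fell in 9 of 19 cases and rose in 4, with 6 not passing, and 10 and 4 over the list alone. Elane fell by 2.30, Ms4a3 by 1.84 (SE 0.104, adjusted p = 1.46e-05), the lectin receptor Clec12a by 1.49 and Spi1, which encodes the transcription factor PU.1, by 0.62. Fcgr3, an Fc receptor, rose by 0.82. Ctsg differed by -0.92 without passing (adjusted p = 0.0829, in a range of 0.0376 to 0.185), and it passed without DKO replicate 2 (0.0458, at -0.44) or 3 (0.0461, at -1.21), with cyclic loess and with the block. The list was called lower (mean -0.44 ± 0.81, adjusted p = 0.0146, and adjusted p = 0.512 with an estimated correlation), and reached 0.053 without WT replicate 2. Lymphoid priming genes fell in 7 of 22 cases with 0 rises and 15 not passing, and 7 fell and 2 rose over the list alone. Dntt, Vpreb1, a part of the pre-B cell receptor (-1.59, adjusted p = 0.0015), Flt3 and Notch1 (-0.63) were among them. This list was called lower (mean -0.38 ± 0.67, adjusted p = 0.016, and adjusted p = 0.548 with an estimated correlation).

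Genes of mature neutrophils and monocytes rose in 2 and fell in 3 of 22 cases, the same over the list alone, with 17 not passing. The rise of Cxcr2 stood against falls of Hp, which encodes haptoglobin, by 2.05, Cybb by 0.82 and Ccr2 by 0.75. Cybb and Ccr2 lay among the dimmest 50% of genes, so the size of their falls is uncertain. The neutrophil gene S100a9 differed by -0.78 (adjusted p = 0.159) and passed without WT replicate 1 (-1.14, adjusted p = 0.0309, in a range of 0.0309 to 0.333), and it was at -0.29 without WT replicate 3. The list was called lower (mean -0.19 ± 0.91, adjusted p = 0.0415, and adjusted p = 0.548 with an estimated correlation), and 11 of 21 alternatives lost the call. Without the dimmest 50% of genes its mean was 0.08, on the other side of 0, while the test still pointed downward (adjusted p = 0.934, the highest of 0.0125 to 0.934). Its mean was -0.11 without WT replicate 3 (0.103), and the call was also lost without DKO replicate 1 (0.0538) or 3 (0.0525).

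Markers of other cell types that the sort removes were not called as lists. Of 21 erythroid genes 0 rose and 3 fell (adjusted p = 0.815), led by Car1, an erythroid carbonic anhydrase, and including Klf1 (-0.54), which missed the threshold without DKO replicate 3 (adjusted p = 0.0526, in a range of 0.0109 to 0.0526). Of 18 B cell genes 1 rose and 1 fell (adjusted p = 0.739), the fall being Cd72, and H2-Aa differed by 1.10 with an SD of 1.3 among the DKO samples (adjusted p = 0.166). It was at 0.45 without DKO replicate 1 (adjusted p = 0.417) and at 1.75 without DKO replicate 2 (0.00978), the ends of its range. Of 22 T and NK cell genes 1 rose and 3 fell (adjusted p = 0.157, and 0.0244, downward, with fry, in a range of 0.0244 to 0.548), with Nkg7, a granule protein gene, falling by 2.02 (adjusted p = 8.42e-06). Of 23 macrophage and dendritic cell genes 1 rose and 4 fell (adjusted p = 0.166), with Cd163 rising by 0.64 and Bst2 falling by 0.54. Of 18 endothelial and stromal genes 0 rose and 1 fell (adjusted p = 0.739), the fall being Pdgfrb by 0.66, a call lost without DKO replicate 1 (0.065) or 3 (0.119) and WT replicate 2 (0.0778) or 3 (0.0989), in a range of 0.00554 to 0.119. Over each list alone the counts were the same, except that 0 endothelial and stromal genes fell.

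Adhesion and homing genes rose in 13 of 25 cases, fell in 1 and did not pass in 11, with 15 and 1 over the list alone. Jam3 rose by 2.45, the integrin chains Itga6, Itga4 and Itgb2 by 1.60, 1.05 and 1.53, and S1pr1, the receptor that guides cells along sphingosine-1-phosphate, by 1.55 (adjusted p = 0.000107). The fall was that of Cxcr4, the receptor for the marrow chemokine Cxcl12 (-0.38, adjusted p = 0.0185), which missed the threshold without DKO replicate 1 (0.0679) or 3 (0.0717), its highest over 18 alternatives. The list had a mean of 0.58 ± 0.69 (adjusted p = 1.29e-07, and adjusted p = 0.0821 with an estimated correlation).

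Interferon-stimulated genes rose in 12 of 28 cases and fell in 1, with 15 not passing, and 13 and 1 over the list alone. Trim30a rose by 1.14 (adjusted p = 0.000101), Xaf1 by 1.06, the ubiquitin ligase gene Herc6 by 0.99, Parp14 by 0.68 and the RNA sensor gene Ddx58 by 0.66. Bst2, which encodes tetherin, fell by 0.54. Iigp1 differed by 1.36 with an SD of 1.1 among the DKO samples and did not pass (adjusted p = 0.0721), although it did without DKO replicate 2 (1.98, adjusted p = 0.00353) and with the replicate number as a block (0.00216), in a range of 0.00216 to 0.22. The list mean was 0.40 ± 0.44 (adjusted p = 1.48e-06, and adjusted p = 0.308 with an estimated correlation). Of 30 inflammatory and NF-kappaB genes 3 rose and 4 fell (4 and 4 over the list alone, adjusted p = 0.696), with the chemokine genes Ccl2 rising by 0.76 and Ccl3 falling by 1.33. Of 25 immediate early and stress genes 1, Klf6, rose by 0.74 and 3 fell, the same over the list alone (adjusted p = 0.271).

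Fanconi anaemia genes, which serve repair of DNA crosslinks, were not called as a list (mean 0.07 ± 0.27, adjusted p = 0.469). The mean was 0.14 and 0.03 without DKO replicates 2 and 3, 0.12 and 0.04 without WT replicates 2 and 3, and 0.03 without X and Y genes. Of 23 members 2 rose, 0 fell and 21 did not pass, the same over the list alone. Fancb rose by 0.93 (6.85 ± 0.25 against 5.93 ± 0.15, adjusted p = 0.00187) and Fancl, the ligase subunit of the core complex, by 0.55 (adjusted p = 0.00374). Brca1 differed by -0.37 (adjusted p = 0.134) and Rad51c by 0.29 (adjusted p = 0.141), with -0.23 for Brca1 without DKO replicate 2 and 0.19 for Rad51c without DKO replicate 3. Of 28 genes of homologous recombination and damage signalling 5 rose and 4 fell, the same over the list alone (adjusted p = 0.865, with a mean and a median of -0.04 and an upward test). The kinase gene Atr and the helicase gene Blm rose by 0.61 and 0.70, and the histone gene H2ax fell by 0.55, with Atr at 0.38 once the trend was removed. Of 24 genes of end joining and excision repair 1 rose and 4 fell, with 1 and 6 over the list alone (adjusted p = 0.739). Prkdc, the catalytic subunit of the DNA-dependent protein kinase, rose by 0.60 (0.38 with the trend removed) and its partner Xrcc5 fell by 0.46.

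Of 21 p53 targets 6 rose and 0 fell, with 7 and 2 over the list alone (adjusted p = 0.102, and 0.0148, upward, with fry, beside 0.0148 to 0.398 over 21 alternatives), and the mean went from 0.17 to 0.35 without the dimmest 50% of genes. Trp53inp1 rose by 1.26 (adjusted p = 0.00114) and Btg2 by 0.64, and Mdm2 by 0.43, a call lost without DKO replicate 3 (0.0748, in a range of 0.0112 to 0.0748). Cell cycle inhibitors rose in 4 of 9 cases and fell in 0, with 6 and 1 over the list alone. Cdkn2c rose by 0.66, Cdkn1b by 0.62, Rb1 by 0.50 and the pocket protein gene Rbl2 by 0.47. With the trend removed Rbl2 was at 0.31 and Rb1 at 0.29 without passing (adjusted p = 0.084, in a range of 0.00441 to 0.084), and Cdkn1b was at 0.38 with the mean of its probe sets. Their list was called higher (mean 0.28 ± 0.32, adjusted p = 0.0174, and adjusted p = 0.308 with an estimated correlation), and the call was also lost without the dimmest 25% of genes (0.0512) and on ranks (0.0652), while the mean was 0.48 without the dimmest 50%.

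Of 32 S phase and replication genes 0 rose and 3 fell, but 0 and 0 over the list alone (mean -0.14 ± 0.23, adjusted p = 0.166). Mcm5 fell by 0.66 (adjusted p = 0.0194), a call lost without DKO replicate 2 (0.0673, in a range of 0.0059 to 0.0673). The list was called lower with quantile normalisation (mean -0.23, adjusted p = 0.00199), cyclic loess (-0.22, 0.00159), the trend removed (0.00797), and without DKO replicate 1 (0.0365), DKO replicate 3 (0.0117) or WT replicate 1 (0.0345), in a range of 0.00159 to 0.875. Its mean was -0.21 without DKO replicate 3, -0.06 without WT replicate 2 and 0.00 without DKO replicate 2. Of 33 mitosis genes 2 rose and 0 fell, with 0 and 0 over the list alone (mean -0.01, median 0.00, an upward test, adjusted p = 0.844). The list was called higher without DKO replicate 2 (0.0353, in a range of 0.0353 to 0.987). The estimated correlation between genes was 0.719 for the S phase list and 0.719 for the mitosis list, far above the preset 0.01. Calls of these lists at the preset value may therefore be overstated. Ribosome biogenesis genes rose in 3 and fell in 7 of 30 cases, with 3 and 8 over the list alone (adjusted p = 0.469). Pes1 and Nhp2 fell by 0.81 and 0.78, and this list was called lower with quantile normalisation (0.0175), cyclic loess (0.00954) and the trend removed (0.0182), in a range of 0.00954 to 0.875. Its mean went from -0.09 to -0.17, -0.17 and -0.16 in these fits, and to -0.06 without DKO replicate 2 and -0.05 without WT replicate 2. Of 19 apoptosis regulators 2 rose and 3 fell, with 3 and 3 over the list alone (adjusted p = 0.844, with a mean of -0.05, a median of 0.06 and an upward test, and a mean of -0.03 without DKO replicate 2, -0.08 with quantile normalisation or without X and Y genes and -0.09 with the trend removed). Casp1 rose by 0.81 (adjusted p = 0.000552) beside the fall of Bcl2.

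Of 24 genes described elsewhere as targets of Runx1, 5 rose and 4 fell, with 6 and 5 over the list alone (mean -0.09 ± 0.64, adjusted p = 0.814). Itga2b and Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 0.92 and 0.60, and Elane and Spi1 fell by 2.30 and 0.62. The 3 measured members of the Runx family were not called together (adjusted p = 0.835, mean 0.11, median -0.15, and mean -0.12 with the trend removed, 0.18 without WT replicate 2 and 0.06 without WT replicate 3), with 1 rise and, over the list alone, 1 rise and 1 fall.

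**Figure D2:**
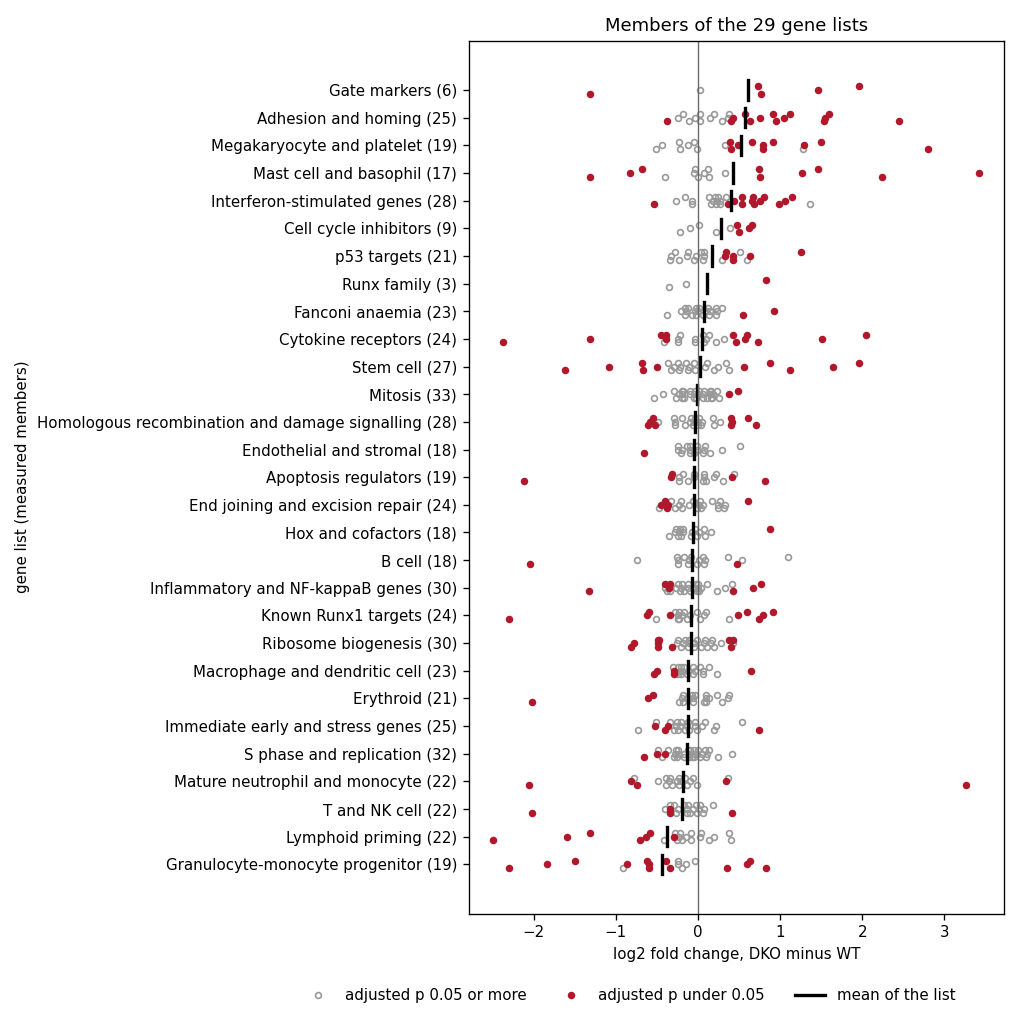
Log2 fold change (DKO minus WT, x axis) of each measured member of the 29 gene lists (y axis, ordered by mean), with filled red circles for adjusted p under 0.05, open grey circles otherwise and black bars for list means. Gate markers (0.60) and adhesion and homing genes (0.58) have the highest means and granulocyte-monocyte progenitor genes (-0.44) the lowest, and most lists hold members on both sides of 0.

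The calls of lists depended on the form of camera: of 6 lists called higher and 3 called lower, 0 were called with an estimated correlation. The estimate lay below the preset 0.01 for adhesion and homing (-0.029), mast cells and basophils (-0.029) and cell cycle inhibitors (-0.062). A larger correlation therefore does not account for their lost calls. For the other called lists the estimate was 0.079 to 0.297. Over 21 alternatives per list, adjusted p ranged from 7.06e-08 to 0.0821 for adhesion and homing, 8.35e-08 to 0.308 for interferon-stimulated genes, 3.43e-06 to 0.512 for megakaryocyte and platelet genes, 0.00253 to 0.308 for gate markers and for cell cycle inhibitors, 0.00218 to 0.308 for mast cells and basophils, 0.000899 to 0.512 for granulocyte-monocyte progenitors, 0.001 to 0.548 for lymphoid priming and 0.0125 to 0.934 for mature neutrophils and monocytes.

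Genes of the Y chromosome also differed between the groups. The sex of the mice in each sample is not given in the labels, which do not say whether the groups held the same mix of sexes. Uty rose by 0.82 (7.61 ± 0.09 against 6.79 ± 0.01, adjusted p = 0.000355), Kdm5d by 0.67 (adjusted p = 0.00148) and Eif2s3y by 0.44 (adjusted p = 0.0136). The call of Eif2s3y was lost with quantile normalisation (0.0743), cyclic loess (0.0504), the trend removed (0.103) and without DKO replicate 2 (0.0571) or 3 (0.0519), in a range of 0.00836 to 0.103. Xist, the RNA of the inactive X chromosome, differed by -0.44 (adjusted p = 0.0643) and passed without WT replicate 1 (adjusted p = 0.00738, in a range of 0.00738 to 0.19). Xist lay among the dimmest 25% of genes, so the size of its difference is uncertain. Uty lay above the median of all genes, 6.02, in both groups. These signals were not used to assign a sex to the samples. Without genes on chromosomes X and Y, 1860 genes rose and 1509 fell.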

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

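Probe sets left out of the gene comparison, because the annotation used gives them no symbol or several, also differed between the groups. Tested on their own with limma, 616 of 13767 were higher and 398 lower in the DKO-labelled samples, and 3383 had an unadjusted p under 0.05. Of 1621 probe sets with several symbols, 50 were higher and 65 lower, and of 12146 with no symbol, 566 were higher and 333 lower. What these probe sets measure was not analysed here.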

How the results depend on the processing

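The fits with the trend removed and without X and Y genes were chosen after the data were seen. Under changes of normalisation, filter and variance model the counts of genes were 1476 to 2032 higher and 1269 to 1576 lower, and 0 calls passed in the opposite direction. With all 35556 probe sets as features, 2481 were higher and 1646 lower, and 1372 of the 1936 and 908 of the 1533 calls were kept. Leaving out 1 sample gave 1250 to 1868 higher and 843 to 1388 lower, with fewer samples in the test. Thresholds on size set the count: 873 higher and 458 lower at adjusted p under 0.05 and 1.5-fold, 889 and 474 at unadjusted p under 0.05 and 1.5-fold, and 225 and 110 at 2-fold. The replicate number did not pair samples: deviations of samples with the same number correlated at -0.009, -0.095 and -0.042, no sample correlated best with its own number, and with the number as a replicate block 1772 genes were higher and 1272 lower. Lists called higher and lower fell from 6 and 3 to 0 and 0 with an estimated correlation, and to 3 higher on ranks, and fry gave 7 and 4. Runx1 stayed past the threshold under all 18 alternatives (0.502 to 0.859), whereas Runx3 moved from -0.15 to -0.299 with the trend removed. The cause was not tested. Of 135 named genes 114 passed the threshold, and 86 of these passed it in the same direction under every alternative run. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. Counts as large as the real one came from 1 of 10 splits for genes higher (1936, highest other 0) and 1 of 10 for genes lower (1533, highest other 0), and from 2 of 10 for lists higher (6, highest other 7) and 4 of 10 for lists lower (3, highest other 6). Each other split sets 2 samples of 1 group and 1 of the other against the rest. Part of a group difference therefore remains in it, and its calls of lists do not measure chance alone. Of the 9 other splits, 6 called adhesion and homing in either direction and 5 called interferon-stimulated genes. Megakaryocyte and platelet genes and mature neutrophils and monocytes were called in 3 each, granulocyte-monocyte progenitors in 2 and lymphoid priming in 1. Cell cycle inhibitors, mast cells and basophils, and gate markers were called in 0. Among lists that the real split did not call, S phase and replication was called in 6 and mitosis in 7.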

Other observations

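In this part, the test of gene families, the removal of the trend, and the tests on cell types, on an exchange of samples, on RNA quality and on probes were chosen only after the result was seen.

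Gimap genes, which encode small GTPases of lymphocytes and lie side by side in the genome, rose as a family in the DKO-labelled samples. All 8 measured members passed the threshold, with a mean of 1.06 on the log2 scale and 1.01 to 1.08 over 4 other scalings, although Gimap1 missed it with quantile normalisation and cyclic loess. Gimap4 rose by 1.95, Gimap7 by 1.34 and Gimap9 by 1.29, and 5 of the 8 passed under each of 18 alternatives. The call was lost for Gimap1 (adjusted p up to 0.0833, without DKO replicate 2), Gimap3 (up to 0.0744, without DKO replicate 3) and Gimap5 (up to 0.0664, without WT replicate 1) when 1 sample was left out, and Gimap3 was at 0.64 without WT replicate 2. With all probe sets as features, Gimap3 and Gimap5 also missed the threshold (limma adjusted p = 0.0759 for each). Bex genes moved the other way: 4 of 5 fell, with a mean of -1.43 (-1.425 to -1.355 over 4 other scalings). With quantile normalisation or cyclic loess 5 of 5 fell. The falls were led by Bex1 (-3.11), Bex4 (-1.82, to a dim 4.26) and Bex6 (-1.42). Bex2 missed the threshold without DKO replicate 2 (0.0612), DKO replicate 3 (0.0522) or WT replicate 2 (0.053). Both are families of similar genes, so the share of each member is uncertain. Of 594 families of gene symbols tested with limma's camera, 14 were called higher and 1, Bex, lower (adjusted p = 4.47e-06 for Gimap and 0.000415 for Bex), and both had adjusted p = 0.957 with an estimated correlation.

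Signals of genes for small nucleolar RNAs, which guide modification of ribosomal RNA, also differed. Whether these signals reflect the small RNAs themselves was not tested. Of 31 Snord genes 12 rose and 3 fell, and of 20 Snora genes 10 rose and 2 fell (adjusted p = 0.0109 and 0.0206, and 0.957 for both with an estimated correlation).

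Long and strongly expressed genes were higher in the DKO-labelled samples. Over the 50% of genes with the stronger signal, log2 fold change correlated with gene span at rho = 0.261, across genes, which are not independent replicates, and medians over 10 classes of span ran from -0.101 in the shortest to 0.161. The trend as the whole cause of the calls is argued against, because 69.4% of the higher and 77.4% of the lower calls passed in the same direction after its removal. A difference in RNA quality or amplification between the groups stays open: within groups the correlation with span varied by 0.049 between arrays, beside a difference of 0.232 between the groups, and no measure of RNA quality was used. An effect of the genotype on long genes is an untested alternative, and these explanations cannot be told apart here.

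In cells sorted against mature lineages, 6 of 17 mast cell and basophil genes rose and 3 fell, and 10 of 19 platelet genes rose, so that other cells within the gate may be a source of these rises. Mature basophils would raise Mcpt8, Prss34 and Fcer1a with Cpa3, and their mean log2 fold change was -0.943 (SE 0.18). They were the 3 members of their list that fell and were chosen after their values were seen. Their mean therefore does not decide on mature basophils. Mcpt8 (-1.32) and Prss34 (-0.82) had a mean signal above the median of all genes, whereas Fcer1a lay below it. Pf4 and Ppbp, which platelets or ordinary megakaryocytes would raise about as much as Gp5 (2.80), had a mean of -0.476 (SE 0.435). Both were chosen after their values were seen and depended on single samples, and Pf4 is itself listed among Runx1 targets. Their mean therefore does not decide on platelets or megakaryocytes. For mature mast cells the mean of 0.029 for Cma1, Mcpt4, Tpsb2 and Tpsab1 decides nothing either. Their mean signal of 4.33 lay below the median of all genes, 6.02. A hypothesis left open and not tested is that the genotype changes the mast cell and platelet genes that rose, or the mix of progenitors, within the KSL gate.

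The gene that was to be deleted had more signal, not less, in the samples labelled DKO. An exchange of 1 sample between the groups is argued against, since each array's lowest correlation with its own group exceeded its highest with the other by at least 0.0098. Of the 2 targeted genes, 0 fell past the threshold, although Runx3 did with the trend removed (-0.299, adjusted p = 0.0362, beside 0.0362 to 0.46 over its alternatives), in the direction of the labels. Probes outside the deleted exons could keep the Runx1 signal from falling but would not by themselves raise it. With probe positions not used here, exchanged group labels stay open. No biological explanation was tested.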
